A study of Macaca mulatta with 12 samples.

How the data were processed

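Rhesus macaque testis was profiled by droplet single-cell RNA sequencing, with cells dissociated from fresh tissue in type IV collagenase and libraries built with the 10x 3′ v2 chemistry, per the labels' protocols. Per the submitters' processing notes, reads were processed with Cell Ranger, whose version is not given, on the rheMac10 genome. The labels list 12 samples in 6 groups of 2, made of 3 ages (1, 6 and 22 years) and the states BR and Non-BR. The labels do not say what BR stands for, and it is used here only as a group name. The deposited table holds the cells of 8 of these samples, and the other 4 were not used here. The 8 libraries were 1-year Non-BR replicate 2, 1-year BR replicates 1 and 2, 6-year Non-BR replicate 2, 6-year BR replicate 1, 22-year Non-BR replicate 2, and 22-year BR replicates 1 and 2.

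The values deposited by the authors are a raw count of unique molecular identifiers (UMIs) per gene and cell, and all of them were whole numbers. The table held 62587 cells, 20066 genes and 119719982 UMIs. No cell had under 343 UMIs or under 299 genes, so a filter had been applied before deposit. No further cell filter was applied, and doublets were not searched for. Of the genes, 15166 were given a symbol from a separate reference of gene names, matched by identifier, and the other 4900 were kept under their identifier. Symbols carried by several identifiers, 204 genes in all, were kept as separate genes. The authors' annotation gave each cell an age, a state and 1 of 16 cell types, and the age and state matched the labels for all 62587 cells. The replicate of a cell was taken from the sample code in its name and was not checked further. These types were used as cell classes under the names the annotation gives (SSC.u, SSC.d, L, Z, P, D, SPD.r, SPD.e, Sertoli.f, Sertoli.a, Leydig, PMC, Endothelial, Macrophage, Lymphocyte, Epithelial), except that Sertoli.f and Sertoli.a were merged as Sertoli because no library held both. Here SSC.u and SSC.d are read as spermatogonia, L, Z and P as spermatocytes, and SPD.r and SPD.e as spermatids, from the markers they expressed. D is counted with the spermatocyte classes, although no measured spermatocyte marker peaked in it. The abbreviations themselves were not expanded. The annotation was compared with 16 marker lists, each written before the data were examined, as were the gene lists, the tests, the rule for named genes and the first set of alternatives.

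UMIs were summed per library and class into pseudobulk counts wherever a library had at least 20 cells of the class. Differences were tested with edgeR 4.0.16 in R 4.3.3 (filterByExpr, TMM factors, glmQLFit and glmQLFTest, two-sided), with Benjamini-Hochberg adjustment within class and contrast and a threshold of 0.05. The planned model gave each group of age and state its own mean and tested only groups of 2 samples. With 8 of 12 samples in the table that rule left no contrast to test. After the sample list was seen and before any test result, an additive model of age plus state was therefore taken as the reported fit for the state over ages and for both age contrasts. The age contrasts so combine BR and Non-BR libraries, although the plan was to compare Non-BR libraries alone. For these contrasts the planned model of groups is given as an alternative, with the rule of 2 samples per group dropped. The state at 1 year, the state at 22 years and the change of the state's effect between ages were tested in the model of groups, where the spread is pooled over groups and a lone library is assumed to vary like the others. The state at 6 years, 1 library against 1, is given as values with no test. In the additive model, residual degrees of freedom were 2 in SSC.d, the spermatocyte and spermatid classes, 3 in Sertoli, Leydig and Endothelial, and 4 in PMC and SSC.u. In the model of groups they were 2 in SSC.u, PMC and Endothelial and 1 in the other classes.

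The labels carry 6 sample codes for the 8 libraries, and 2 codes, those of 1-year and 22-year replicate 2, have a library of each state. The labels do not say whether a code stands for an animal. If it does, libraries sharing a code are not independent, and p-values of the age contrasts are too small. The replicate block could be fitted over ages only in PMC and SSC.u, and a correlation between paired libraries was not computed because only 2 pairs exist. A block with the state nested in age left 0 degrees of freedom and was not run.

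Gene lists, 35 in number, were tested with camera in limma 3.58.1 on the same counts with an inter-gene correlation of 0.01, for lists with at least 5 tested members, adjusted over all lists and classes of a contrast. Each was tested again with the correlation estimated from the data. That version passed no list in any contrast, not even a list of spermatid transcripts of which every tested member rose, so not passing it does not argue against a list. Shares of classes were compared between states by an exact two-sided permutation test of the mean within-age logit difference, with 0.5 cells added, permuting states within age, and adjusted over 16 classes, all germ cells among them. Shares were compared between ages by an exact two-sided permutation of libraries, a test added after the results were seen. Shares carry exact Clopper-Pearson 95% intervals, which cover counting error only. Where a gene had no UMI in a group, a floor of 3 UMIs over the group's summed UMIs stands in for its level, and the fold is given as a bound.

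Genes are named by this rule. In the 5 classes with most calls of each main contrast, the 2 largest rises and falls are named among called genes with a symbol, at least 20 CPM (UMIs scaled to a common library total) in the higher group, and the same direction in each pair of a replicate number for the state, or no overlap of groups for age. Their class mean had to be no more than 5-fold below the highest class mean, since free RNA of another class could give a lower level. Up to 4 members of each called list with the smallest adjusted p were added, and marker genes fixed in advance were followed in the class they mark. In the contrasts of the state within an age and between ages, at most 4 genes each are named. Genes chosen after their values were seen are said to be so.

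The alternatives were DESeq2 1.42.0, RLE factors, no count filter, a minimum of 50 cells, genes more than 5-fold below another class left out, cells under 1000 UMIs left out, each library left out in turn, and the replicate block. The use of the model of groups with lone libraries was decided after the sample list was seen, and the removal of genes at 300 CPM or more in spermatids before the fit was added after the data were seen. The other splits of the libraries within age were fitted as well. The pipeline was tested on simulated counts with the depths of the real libraries, in which 200 genes were changed, 100 of them by a fold of 2 and 100 by a fold of 4. In Sertoli cells at 6 against 1 year, 20 of the 2-fold and 92 of the 4-fold changes were called, with 4 unchanged genes. In PMC between states these were 40 and 85, with 6 unchanged genes, and in SSC.u 34 and 81, with 1 unchanged gene. In D between states 41 and 89 were called, with 6 unchanged genes. With nothing changed, 0 genes were called. Changed genes had a mean of at least 20 CPM, and no other effect of age or sample code was simulated. In PMC the 200 changed genes were among 1007, while the real contrast between states called 0 there. A larger share of changed genes loosens the adjusted threshold, so the PMC rates may overstate what the real test could find. Tables and figures were made with Python 3.11.15, numpy 2.4.6, scipy 1.17.1, pandas 2.3.3 and matplotlib 3.10.9.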

Results

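The data were UMI counts of single cells from rhesus macaque testis at 1, 6 and 22 years of age, in the states labelled BR and Non-BR. At 1 year there were 1 Non-BR and 2 BR libraries, at 6 years 1 of each, and at 22 years 1 Non-BR and 2 BR libraries. The libraries held 5180 to 9886 cells, and the median cell had 1006 to 2135.5 UMIs. Library totals ran from 11869819 UMIs (22-year BR replicate 1) to 18175213 UMIs (6-year Non-BR replicate 2). At 1 year they were 15860568 in Non-BR replicate 2, 14143428 in BR replicate 1 and 13904837 in BR replicate 2. The others were 16960822 in 6-year BR replicate 1, 16186961 in 22-year Non-BR replicate 2 and 12618334 in 22-year BR replicate 2. Mitochondrially encoded RNA, from 10 genes, took 0.105 to 0.478% of the UMIs of a library. Transcripts of PRM1, which encodes a protamine that packs sperm DNA, took 2.93 to 8.17% of the UMIs of the adult libraries, meaning those at 6 and 22 years, and had no UMI in any 1-year library.

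The make-up of the tissue was compared across ages. Sertoli cells, which nurse the germ cells, were 77.9, 69.0 and 83.2% of cells in the 3 1-year libraries, all under the annotation Sertoli.f. At 6 years, under Sertoli.a, they were 18.1% (95% interval 17.3 to 19.1) in the Non-BR and 3.38% (2.98 to 3.81) in the BR library. At 22 years they were 1.17% in the Non-BR library and 0.386 and 0.0425% in the BR libraries. Germ cells were 1.2, 2.16 and 1.37% of cells at 1 year, all of them SSC.u. They were 79.6% (78.7 to 80.5) and 94.2% (93.7 to 94.7) at 6 years, Non-BR first, and 96.0, 96.6 and 98.7% at 22 years. The elongating spermatid class SPD.e was 16.7% of 6-year Non-BR and 47.4% of 6-year BR cells, and 39.5, 27.6 and 35.8% of cells at 22 years. Exact intervals of all shares were at most 2.64 percentage points wide, so the 1-year BR libraries, at 69.0 and 83.2% Sertoli cells, differed by more than counting error. Between ages, with both states together, the mean logit share from 1 to 6 years differed by -3.65 for Sertoli cells and 6.24 for germ cells (exact two-sided permutation p 0.1 for each). From 6 to 22 years it differed by -3.43 for Sertoli cells (exact permutation p 0.2) and 1.53 for germ cells (0.1). With 3 libraries against 2 there are 10 arrangements, so no share could fall under an exact p of 0.1.

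**Figure D1:**
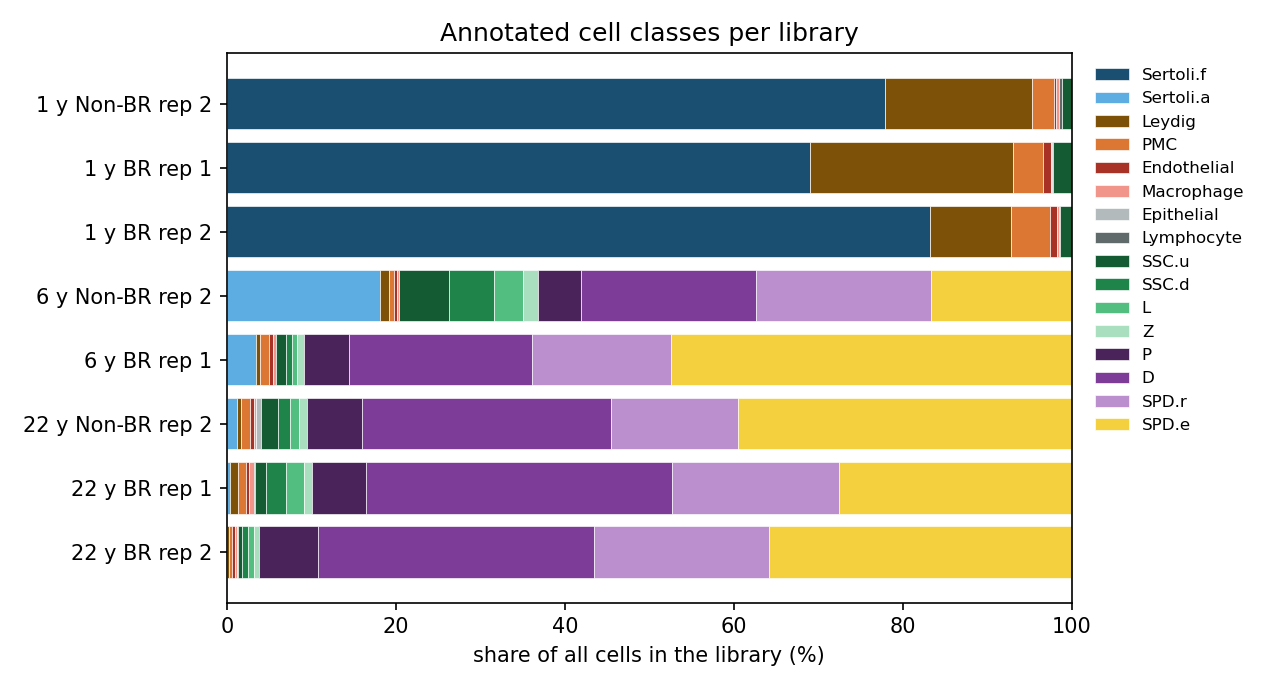
Stacked bars give the percent of cells (x axis) of each annotated class in each of the 8 libraries (y axis). Sertoli cells were 69.0 to 83.2% of 1-year cells and germ cells 79.6 to 98.7% of adult cells.

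The annotation was compared with marker genes. All 12 measured markers of elongating spermatids were highest in SPD.e, all 8 of endothelium in Endothelial, all 10 of macrophages in Macrophage and all 10 of T or NK cells in Lymphocyte. Round spermatid markers peaked in SPD.r for 8 of 12, and those of undifferentiated spermatogonia in SSC.u for 7 of 12, among them UTF1 at 959 CPM. Of 8 markers of differentiating spermatogonia, 4 peaked in SSC.d. Of 15 spermatocyte markers, 5 peaked in L, 6 in Z, 3 in P, 1 in SSC.u and 0 in D, so markers did not identify D. Of 17 Sertoli markers, 7 peaked in Sertoli.f and 7 in Sertoli.a, and 6 of 9 peritubular myoid markers peaked in PMC. The annotated Leydig cells carried the markers of interstitial stroma, with 9 of 10 highest there and DCN, a matrix proteoglycan, at 5989 CPM. CYP17A1, a steroid-synthesis enzyme of androgen-making Leydig cells, was at 4.34 CPM in the class named Leydig and 136 CPM in PMC, and INSL3 at 1.73 and 13.7 CPM. Results for Leydig below therefore describe cells with a stromal profile.

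The first question of age was which genes differ between 1 and 6 years, before and after germ cells fill the tubules, and Sertoli cells changed most. CST9L (ENSMMUG00000045312.2), a cystatin-family gene expressed by Sertoli cells, rose from 6.27 ± 3.62 CPM (SD, n = 3) at 1 year to 7297 ± 8.84 CPM (n = 2) at 6 years, by 10.40 ± 0.42 on the log2 scale (SE, edgeR adjusted p 2.41e-08). SPINLW1 (ENSMMUG00000003806.4), an epididymal protease inhibitor gene, rose from 0.245 ± 0.358 to 1026 ± 93.4 CPM, and PRND, the gene of the prion-like protein doppel, from 0.271 ± 0.342 to 794 ± 143 CPM. CLDN11 (ENSMMUG00000059260.1), a claudin of the tight junctions between Sertoli cells, rose by 4.21 ± 0.27 (edgeR adjusted p 1.07e-06), from 57.7 ± 9.57 to 906 ± 25.1 CPM. CPXM1 and ANXA3 had no UMI at 6 years, at least 87.6-fold and 79.2-fold lower than the 104 ± 30.2 and 94.4 ± 21.0 CPM of 1 year. SOX9, a Sertoli identity factor, and INHA, the inhibin alpha gene, were not called, with log2 differences of -0.16 (edgeR adjusted p 0.722) and 0.41 (0.255). AMH, the anti-Müllerian hormone of immature Sertoli cells, averaged 7044 ± 553 CPM at 1 year, 2930 ± 1034 at 6 and 840 ± 313 at 22 years (2 libraries of 105 and 20 cells). Its log2 difference of -1.06 ± 0.35 from 1 to 6 years had an edgeR adjusted p of 0.0432. That call depended on 4 libraries, with an edgeR adjusted p for AMH of 0.0659 without 1-year Non-BR replicate 2, 0.110 and 0.118 without 1-year BR replicates 1 and 2, and 0.245 without 6-year Non-BR replicate 2.

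**Figure D2:**
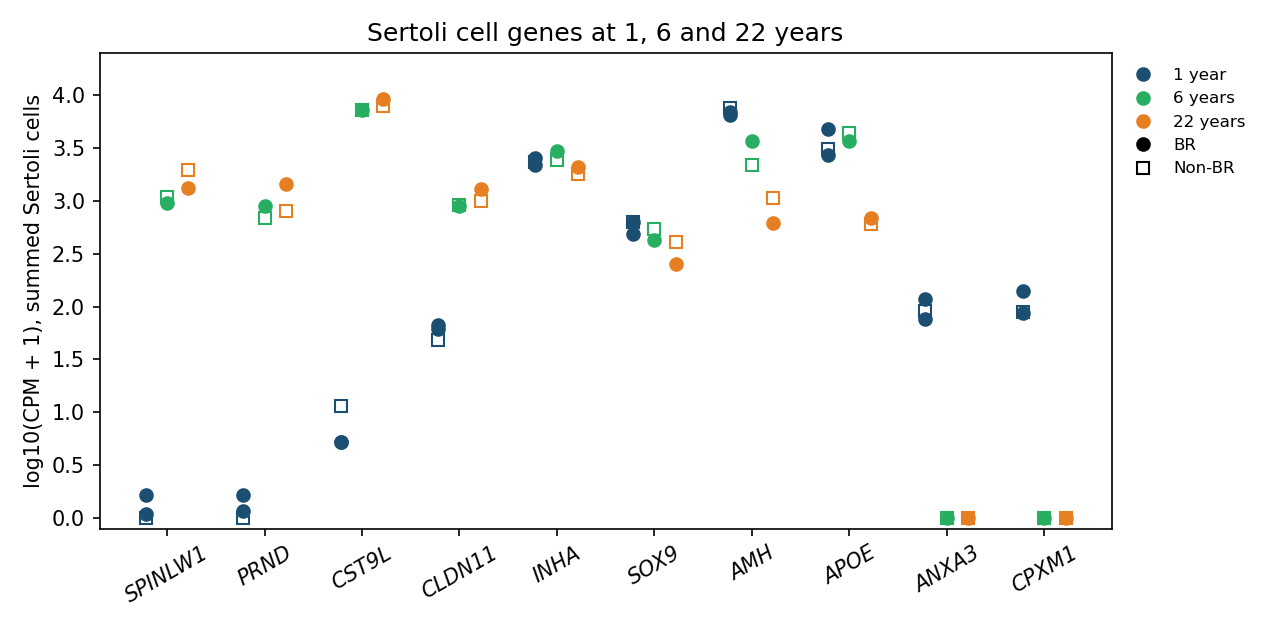
Points give log10 of CPM plus 1 (y axis) of Sertoli pseudobulks for 10 genes (x axis), 1 point per library, coloured by age, with BR filled and Non-BR open. CST9L, SPINLW1 and PRND lay far higher at 6 and 22 years than at 1 year, and CPXM1 and ANXA3 lay at 0 in the adult libraries.

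Camera called lists of Sertoli genes from 1 to 6 years, but none of them passed with an estimated correlation. The free spermatid RNA probe, with all 7 tested genes rising, did not pass it either (0.171), so that version cannot decide against these lists. That adjusted p was 0.286 for Sertoli function, 0.270 for cell junctions, 0.611 for interferon response, 0.623 for immediate-early genes, 0.270 for mitochondrially encoded genes, 0.644 for glycolysis, 0.784 for ribosomal proteins and 0.644 for TGF-beta, activin and BMP genes. Of 18 tested genes of Sertoli function, 10 rose and 3 fell (camera adjusted p 2.54e-07), and adjusted over the list alone 10 rose and 4 fell. Of 20 cell junction genes 9 rose, among them JAM3 by 3.07 and NECTIN3 by 2.36 on the log2 scale, and 2 fell, with CLDN3 at -3.41 (list camera adjusted p 0.000994). Counts were the same adjusted over the list alone. Of 24 interferon response genes 16 fell (18 adjusted over the list alone; camera adjusted p 5.2e-05). MX1, an antiviral GTPase gene, fell from 109 ± 25.8 to 10.3 ± 1.91 CPM, and BST2 had a log2 difference of -5.13. Of 24 immediate-early genes, which respond to stress and tissue dissociation within minutes, 13 fell (16 adjusted over the list alone; camera adjusted p 5.61e-05), with ATF3 at -4.85. Mitochondrially encoded genes rose in 6 of 9, with COX1 at 3.12 and ND4 at 2.41 (6 adjusted over the list alone; camera adjusted p 0.000644). Glycolysis genes rose in 7 of 21 (7 adjusted over the list alone, with 1 fall; camera adjusted p 0.0415), PFKL by 4.36. Ribosomal protein genes fell in 39 of 70 (50 adjusted over the list alone; camera adjusted p 4.76e-08), RPL31 by 2.22, and TGF-beta, activin and BMP genes fell in 6 of 18, with 1 rise (7 and 1 adjusted over the list alone; camera adjusted p 0.0476). Spermatid transcripts rose in the same cells, whether as free RNA or from doublets, which were not searched for. PRM1 went from no UMI at 1 year to 2999 CPM in Sertoli cells at 6 years, at least 38140-fold higher, and all 7 tested genes of the free spermatid RNA probe rose (camera adjusted p 4.44e-20, 0.171 with an estimated correlation). Germ cell lists also rose there, with 5 of 7 histone replacement genes (4.17e-12), 9 of 17 axoneme genes (5.31e-06), 5 of 8 piRNA genes (0.00153) and 6 of 11 acrosome genes (0.0145, all camera adjusted p and none of them past 0.05 with an estimated correlation).

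In PMC, the class with myoid markers, contractile transcripts were higher at 6 years. ACTA2 (ENSMMUG00000009341.4), smooth muscle actin, rose from 1480 ± 845 CPM (SD, n = 3) to 11152 ± 5372 (n = 2), by 3.04 ± 0.32 on the log2 scale (SE, edgeR adjusted p 0.00066). GSN, encoding the actin-severing protein gelsolin, rose from 93.1 ± 43.3 to 1972 ± 1148 CPM (log2 4.44, edgeR adjusted p 6.89e-05) and MYLK, the myosin light chain kinase gene, from 252 ± 30.9 to 2095 ± 221 CPM. Of 15 tested smooth muscle genes 11 rose (13 adjusted over the list alone; camera adjusted p 1.13e-09), of 19 collagen and matrix genes 9 rose (10 adjusted over the list alone; 1.5e-06), and of 67 ribosomal protein genes 46 fell (56 adjusted over the list alone; 6.49e-19). With an estimated correlation their adjusted p were 0.310, 0.295 and 0.136. Spermatid transcripts differed too, since PRM1 in PMC was at least 4093-fold higher at 6 than at 1 year. Markers of other cells were higher in PMC at 6 years too, so the mix of cells within the class was not held constant. DCN, of stroma, averaged 2299 ± 481 CPM at 1 year and 6898 ± 102 at 6 years, and RGS5, of pericytes, was at 14.1, 204 and 338 CPM in the 1-year libraries and 141 and 639 CPM at 6 years, a difference that was not called (edgeR adjusted p 0.172). The edgeR adjusted p of DCN was 0.00721, with 0.169 in the model of groups, 0.0653 without 6-year Non-BR replicate 2 and 0.155 without 6-year BR replicate 1. The myosin gene MYH11 rose from 543 ± 114 to 2227 ± 612 CPM (log2 1.95, edgeR adjusted p 0.00843), but without 6-year BR replicate 1 its log2 difference was 1.49 with an edgeR adjusted p of 0.292, and in the model of groups the edgeR adjusted p of MYH11 was 0.153. In all, 95 PMC genes rose and 79 fell, and this count of 174 was 107 and 96 without 1-year BR replicates 1 and 2, 56 without 6-year Non-BR replicate 2 and 9 without 6-year BR replicate 1.

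**Figure D3:**
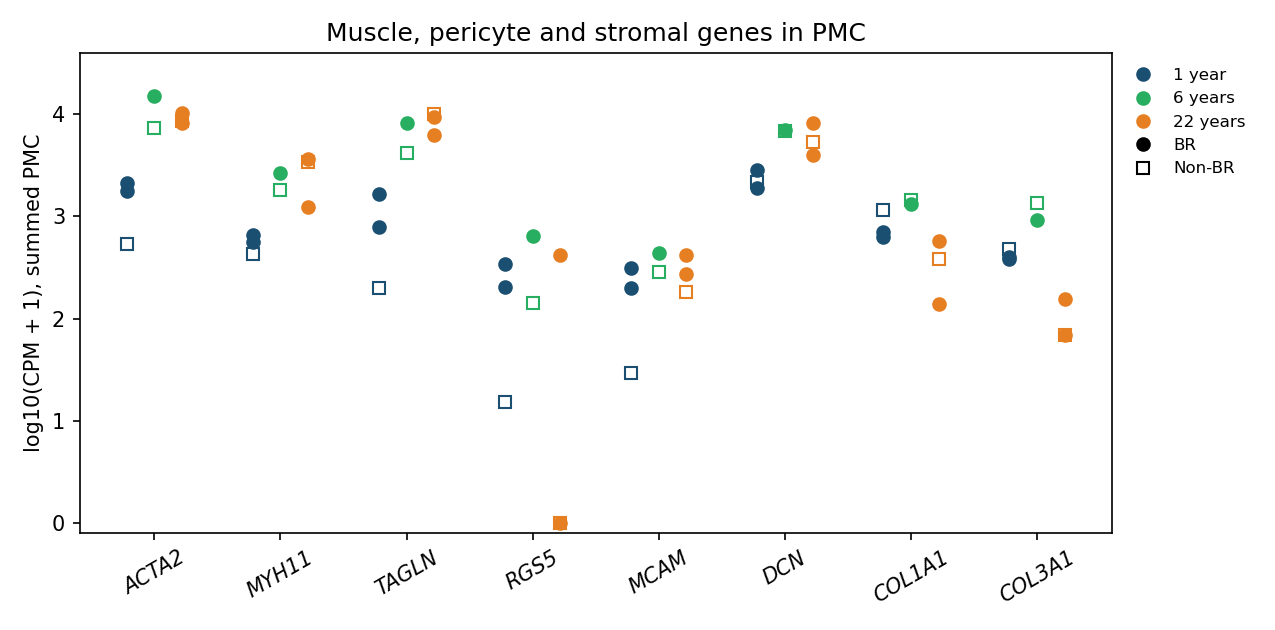
Points give log10 of CPM plus 1 (y axis) of PMC pseudobulks for 8 genes (x axis), 1 point per library, coloured by age, with BR filled and Non-BR open. ACTA2 averaged 1480 CPM at 1 year and 11152 CPM at 6 years, and COL3A1 averaged 96.2 CPM at 22 years.

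In the annotated Leydig cells, CLEC3B (ENSMMUG00000051139.1), encoding the plasminogen-binding protein tetranectin, rose from 23.2 ± 5.44 CPM (SD, n = 3) to 1810 ± 776 (n = 2), by 6.33 ± 0.41 on the log2 scale (SE, edgeR adjusted p 0.000162). PI16, a marker of stem-like fibroblasts in other tissues, rose from 54.0 ± 20.3 to 1070 ± 555 CPM, by 4.47 ± 0.30 (edgeR adjusted p 0.000162), although in the model of groups, with Non-BR libraries alone, its edgeR adjusted p was 0.117. Of 21 collagen and matrix genes 8 rose and 1 fell (10 and 2 adjusted over the list alone; camera adjusted p 0.00424, and 0.286 with an estimated correlation), and of 67 ribosomal protein genes 15 fell (48 adjusted over the list alone; camera adjusted p 4.17e-12, and 0.189 with an estimated correlation). Immediate-early genes were lower in 13 of 16, with 1 called (camera adjusted p 0.000344, and 0.644 with an estimated correlation). Mitochondrially encoded genes were higher in 5 of 5, with 1 called (camera adjusted p 0.0235, and 0.718 with an estimated correlation). A difference in dissociation or RNA quality between the ages was not separated from age. DLK1, a gene of immature stromal cells, went from 785 ± 306 to 181 ± 101 CPM (log2 -2.00, edgeR adjusted p 0.0303), with an edgeR adjusted p of 0.0981 without 1-year Non-BR replicate 2, 0.0961 without 1-year BR replicate 2, 0.0821 without 6-year BR replicate 1 and 0.2 in the model of groups. PRM1, a spermatid transcript, was at least 18693-fold higher at 6 years in this class too. In all 50 Leydig genes rose and 26 fell. Their count of 76 was 45 without 1-year Non-BR replicate 2, 42 and 26 without 1-year BR replicates 1 and 2, 280 without 22-year Non-BR replicate 2 and 284 without 22-year BR replicate 1.

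SSC.u cells gave fewer calls than Sertoli, PMC and Leydig in the additive model, but more than PMC and Leydig in the model of groups. UTF1, a chromatin factor of undifferentiated spermatogonia, was not called, at 988 ± 110 CPM (SD, n = 3) at 1 year and 878 ± 160 (n = 2) at 6 years (log2 -0.24, edgeR adjusted p 0.988). FOS, an immediate-early gene, fell from 451 ± 198 to 53.1 ± 2.99 CPM (log2 -3.05, edgeR adjusted p 0.00287). AMH in SSC.u went from 490 ± 43.4 to 12.7 ± 3.59 CPM (log2 -5.15), beside its 7044 CPM in 1-year Sertoli cells, and 2 of 8 tested Sertoli function genes fell in SSC.u (5 adjusted over the list alone; camera adjusted p 1.17e-12, and 0.158 with an estimated correlation). PRM1, a spermatid transcript, was in SSC.u at 463 CPM in the 6-year Non-BR and 5872 CPM in the 6-year BR library. Their mean of 3167 CPM was at least 1248-fold higher than at 1 year, a bound carried mostly by the BR library. In SSC.u 2 genes rose and 63 fell. That count of 65 was 200 without 1-year Non-BR replicate 2, 13 and 24 without 1-year BR replicates 1 and 2, 9 without 6-year Non-BR replicate 2 and 129 without 6-year BR replicate 1. In Endothelial 2 genes rose and 5 fell, among them RAMP3, a receptor-modifying protein gene, which went from 166 ± 67.2 to 987 ± 350 CPM (SD, n = 2 for each, edgeR adjusted p 0.0458). The 1-year Non-BR library, with 19 Endothelial cells, did not enter, so both 1-year values are of BR libraries. Its edgeR adjusted p was 0.146 and 0.319 without 1-year BR replicates 1 and 2, 0.0862 without 6-year BR replicate 1 and 0.147 without 22-year BR replicate 2. The Endothelial count of 7 was 1 and 2 without 1-year BR replicates 1 and 2, 13 and 18 without 6-year Non-BR replicate 2 and 6-year BR replicate 1, and 1 without 22-year BR replicate 2.

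Over all classes of the 6 against 1 year contrast, 18625 tests were made, 4750 had an unadjusted p under 0.05 and edgeR called 2810, of which 1211 rose and 1599 fell. Sertoli cells gave 2488 of these, 1062 rises and 1426 falls. The Sertoli count was 1496 without 1-year Non-BR replicate 2, 1657 and 1395 without 1-year BR replicates 1 and 2, and 1387 without 6-year Non-BR replicate 2. The Non-BR libraries alone, 1 against 1 with a spread pooled from the other groups, gave 2785 calls in place of 2810, but 16 in place of 174 in PMC, 2 in place of 76 in Leydig and 187 in place of 65 in SSC.u. With genes at 300 CPM or more in spermatids left out before the fit, 2321 were called, 1039 higher and 1282 lower. Of 109 list tests camera called 30, of which 20 were up and 10 down, and 0 with an estimated correlation.

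The second question of age was what differs between 6 and 22 years. At 22 years BR replicate 2 had 3 Sertoli cells and did not enter for that class. APOE (ENSMMUG00000014305.4), a lipid carrier gene, fell in Sertoli cells from 4058 ± 522 CPM (SD, n = 2, from 1307 and 254 cells) to 648 ± 56.4 (n = 2, from 105 and 20 cells), with a log2 difference of -2.99 ± 0.36 (SE, edgeR adjusted p 0.0202). Its edgeR adjusted p was 0.0638 without 22-year Non-BR replicate 2 and 0.127 without 22-year BR replicate 1. COL3A1, a fibrillar collagen gene, fell in PMC from 1132 ± 289 CPM (n = 2) to 96.2 ± 49.1 (n = 3), with a log2 difference of -3.55 (edgeR adjusted p 0.0211). Its edgeR adjusted p was 0.0787 and 0.0988 without 1-year BR replicates 1 and 2, 0.139 and 0.117 without 6-year Non-BR replicate 2 and 6-year BR replicate 1, 0.413 without 22-year Non-BR replicate 2 and 0.0602 without 22-year BR replicate 2. PAIP2, encoding a repressor of translation, fell in the spermatocyte class L from 665 ± 168 to 78.5 ± 68.1 CPM (log2 -2.76, edgeR adjusted p 0.00326), with an edgeR adjusted p of 0.696 without 6-year BR replicate 1 and 0.962 without 22-year BR replicate 1. TMBIM6, a gene of the endoplasmic reticulum membrane, fell there by 1.65 on the log2 scale (edgeR adjusted p 0.0462), and its edgeR adjusted p was 0.0519 to 0.999 when any of the 5 adult libraries was left out. In SPD.r 2 genes known by identifier alone, named after their values were seen, were called, ENSMMUG00000043490.2 lower and ENSMMUG00000049502.1 higher. As lists, collagen genes in PMC were lower, with 1 of 19 called and 5 adjusted over the list alone (camera adjusted p 2.56e-05), and so were immediate-early genes in Sertoli cells, with 0 of 24 called by edgeR over all genes and 14 adjusted over the list alone (camera adjusted p 2e-08). With an estimated correlation neither list passed, with an adjusted p of 0.980 for each.

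Over all classes of the 22 against 6 years contrast edgeR called 6 genes, 1 higher and 5 lower, where 3664 tests had an unadjusted p under 0.05, and DESeq2 called 190. Camera called 28 lists, and none passed with an estimated correlation (smallest adjusted p 0.980). The model of groups, with Non-BR libraries alone, gave 304 calls. Without 1 library the count of 6 was 31 (1-year Non-BR replicate 2), 156 (6-year Non-BR replicate 2), 238 (6-year BR replicate 1), 101 (22-year Non-BR replicate 2), 162 (22-year BR replicate 1) and 10 (22-year BR replicate 2). PAIP2, TMBIM6, APOE and COL3A1, the called genes with a symbol, each lost the call without at least 1 library.

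The question of the state was which genes and shares differ between BR and Non-BR libraries of the same age. In the spermatocyte class L, SPCS1 (ENSMMUG00000017370.4), a subunit of the signal peptidase, was at 154 ± 83.5 CPM (SD, n = 3) in adult BR and 700 ± 97.6 CPM (n = 2) in adult Non-BR libraries, a log2 difference of -1.97 ± 0.40 (SE, edgeR adjusted p 0.0157). Left out in turn, the adult libraries gave SPCS1 an edgeR adjusted p of 0.0859 (6-year Non-BR replicate 2), 0.0769 (6-year BR replicate 1), 0.792 (22-year Non-BR replicate 2), 0.660 (22-year BR replicate 1) and 0.102 (22-year BR replicate 2). CCPG1, a gene of autophagy of the endoplasmic reticulum, was lower there by a log2 of -4.93 ± 1.06 (edgeR adjusted p 0.0215), with an edgeR adjusted p of 0.309 without 6-year Non-BR replicate 2 and 0.102 without 22-year BR replicate 2. In the model of groups the edgeR adjusted p of both SPCS1 and CCPG1 in L was 1.00. In the class Z, H1-6, the testis linker histone gene, was at 294 ± 69.5 CPM in BR and 894 ± 558 CPM in Non-BR libraries (log2 -1.53, edgeR adjusted p 0.0401), and without 22-year Non-BR replicate 2 the log2 difference was -0.67 with an edgeR adjusted p of 0.999. The 2 genes called higher in BR, both in L, were the spermatid transcripts PRM1 and HMGB4, and whether they came from free RNA, doublets or misassigned cells was not tested. CCPG1 was also called lower in Z, by a log2 of -3.89 (edgeR adjusted p 0.0285), where no spermatid transcript was called higher. In Z it was named after its values were seen, with a class mean of 58.6 against 400 CPM in another class. In L the BR libraries held CCPG1 at 24.5, 0 and 0 CPM, so its log2 value there bounds no fold. Other called falls were of genes far higher in another class, such as HMOX2 in Z (77.7 against 2306 CPM), though H1-6 was highest in Z. Whether the loss described below touches these falls was not tested. PRM1 was at 523 and 5969 CPM in L of the Non-BR libraries and at 30292, 13895 and 37821 CPM in the BR libraries, a log2 difference of 3.45 (edgeR adjusted p 0.000725). Marker genes followed in the class they mark were not called, with ACTA2 in PMC at 0.93 (edgeR adjusted p 0.504) and PRM1 in SPD.e at 0.25 (0.984).

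Between states over ages, edgeR called 16 of 59235 tests, 2 higher and 14 lower in BR, and 3099 (5.23%) had an unadjusted p under 0.05, close to the 5% that chance alone gives. That share pools classes that differed, with 549 of 7355 tests in P and 73 of 651 in Endothelial, but 291 of 8990 in SPD.r. In L and Z these were 120 of 2478 and 201 of 3598. L gave 8 calls and Z gave 8, and the other 10 classes gave 0, where DESeq2 called 168 over all classes and 0 in L and in Z. The L count was 13 and 20 without 6-year Non-BR replicate 2 and 6-year BR replicate 1, 4 without 22-year Non-BR replicate 2, and 0 and 3 without 22-year BR replicates 1 and 2. The Z count was 34 and 42 without those 6-year libraries, 5 without 22-year Non-BR replicate 2 and 27 without either 22-year BR replicate. The model of groups gave 547 calls in place of 16, so the number of genes that differ between states was not settled by these libraries. Of 275 list tests camera called 26, among them ribosomal protein genes higher in P (camera adjusted p 6.33e-06) and smooth muscle genes higher in PMC (0.0309), with no member of a called list called by edgeR, and none passed with an estimated correlation (smallest adjusted p 0.982). Other splits of the libraries within age gave 15 to 34 list calls, so the list calls do not set the real states apart. The mean within-age logit difference of the germ cell share was 0.818 (exact two-sided permutation p 0.111, adjusted 0.8), and that of Sertoli cells -1.35 (exact permutation p 0.222). No share could pass, since the smallest possible exact p was 0.0556 with the 18 arrangements of 8 libraries, and 0.167 with the 6 arrangements of 5 libraries for D, Epithelial, L, P, SPD.e, SPD.r, SSC.d and Z.

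At 1 year, with 1 Non-BR library, the genes called between states in PMC were smooth muscle genes. RERGL (ENSMMUG00000047016.2), a RAS-like gene of smooth muscle, was at 316 and 273 CPM in the BR libraries and 14.1 CPM in the Non-BR library, a log2 difference of 4.26 ± 0.67 (SE, edgeR adjusted p 0.028), and its edgeR adjusted p was 0.191 and 0.159 without 1-year BR replicates 1 and 2. ACTA2 and TAGLN, both smooth muscle genes and named after their values were seen, were higher by 1.84 and 2.58 on the log2 scale. Smooth muscle genes as a list were higher in PMC of BR libraries, with 2 of 16 called and 5 adjusted over the list alone (camera adjusted p 6.35e-07, and 0.986 with an estimated correlation). Immediate-early genes, a sign of dissociation stress, were higher in the same PMC with the same camera adjusted p, in 16 of 17 members, and in Leydig, also in 16 of 17 (camera adjusted p 0.000151). For these too the adjusted p with an estimated correlation was 0.986, and edgeR called 0 of 17 members in either class (2 in PMC and 0 in Leydig adjusted over the list alone). In Sertoli cells MAFF, a stress-response transcription factor gene, was at 77.8 and 64.7 CPM in BR and 9.48 CPM in Non-BR cells (log2 3.03 ± 0.35, edgeR adjusted p 0.0491), with 0.105 without 6-year Non-BR replicate 2, 0.0561 without 6-year BR replicate 1 and 0.0522 without 22-year Non-BR replicate 2. DESeq2 called neither RERGL nor MAFF. In all edgeR called 12 genes, 8 higher and 4 lower, as 3 in PMC, 5 in Sertoli and 4 in SSC.u, and 0 in Leydig. Over all classes DESeq2 called 2, and 974 of 21274 tests (4.58%) had an unadjusted p under 0.05, no more than the 5% that chance alone gives. This share pools classes that differed, and it was higher in Leydig, which gave no call, than in SSC.u. The PMC count was 0 and 2 without 1-year BR replicates 1 and 2, 7 without 22-year Non-BR replicate 2, and 29 and 38 without 22-year BR replicates 1 and 2. The Sertoli count was 0, 1 and 1 without 6-year Non-BR replicate 2, 6-year BR replicate 1 and 22-year Non-BR replicate 2, and the SSC.u count 0 and 1 without 1-year BR replicates 1 and 2.

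At 22 years most genes called between states were in spermatogonia. EEF1G (ENSMMUG00000006598.4), a translation elongation factor gene, was in SSC.u at 124 and 0 CPM in the BR libraries and 858 CPM in the Non-BR library, a log2 difference of -3.51 ± 0.52 (SE, edgeR adjusted p 5.02e-08, but 0.954 without 1-year BR replicate 1). ISCA1, a gene of iron-sulfur cluster assembly, had no UMI in SSC.u of either BR library, at least 9.87-fold lower than the 281 CPM of the Non-BR library, and its edgeR adjusted p was also 0.954 without 1-year BR replicate 1. COX3, a mitochondrially encoded gene, was in Z at 2160 and 537 CPM in BR and 214 CPM in Non-BR (log2 2.65, edgeR adjusted p 3.67e-07). FBXW12, an F-box gene, was in SPD.r at 133 CPM in BR replicate 1, 3.71 CPM in BR replicate 2 and 0.816 CPM in the Non-BR library, so its call rested on BR replicate 1. DESeq2 called neither COX3 nor FBXW12. Immediate-early genes were lower in PMC of BR libraries, with 4 of 17 called and 9 adjusted over the list alone (camera adjusted p 4.22e-15, and 0.989 with an estimated correlation). EdgeR called 303 genes, 31 higher and 272 lower, of which 175 were in SSC.u, 68 in SSC.d, 39 in Z, 13 in SPD.r, 4 in PMC and 4 in Endothelial. Of all 68911 tests 3590 (5.21%) had an unadjusted p under 0.05, close to the 5% that chance alone gives, and DESeq2 called 66. That share pools all classes. It was higher in SSC.u, which gave most calls, and in Sertoli, and lower in SPD.r and SPD.e, so the pooled value does not describe SSC.u. Of the 163 falls in SSC.u, 69.3% were genes at 300 CPM or more in spermatids, and with such genes left out before the fit the SSC.u count was 15. Without 1-year BR replicate 1 the SSC.u count was 0, and it was 50 without 1-year BR replicate 2 and 102 without 22-year BR replicate 1. The SSC.d count was 45 without 6-year Non-BR replicate 2 and 109 without 6-year BR replicate 1. The PMC count was 62 and 72 without 22-year BR replicates 1 and 2. The Endothelial count was 2 without either 1-year BR replicate, 10 without 6-year BR replicate 1, 51 without 22-year BR replicate 1 and 0 without 22-year BR replicate 2. At 6 years, 1 library against 1, no test was made, and the germ cell share was 94.2% in the BR and 79.6% in the Non-BR library.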

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

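The contrasts of the state's effect between ages were planned. Of the tests of an explanation below, the tests of 1-year spermatogonia and of thinned counts were planned before their result was seen, and the tests of free RNA removal, of spermatid genes alone, of added RNA and of a response were chosen after it. For the response an earlier bound, genes at 300 CPM or more in spermatids over 3 times as frequent among falls as among tested genes, was met and then dropped, because a response may also be concentrated in such genes (7.61 times as frequent). For spermatid genes alone the bound set against removal was met too, and a comparison without PRM1 was then added, because PRM1 made up most of the sum (8.65 with it, 3.76 without it, in 22-year BR replicate 1).

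Genes were called in tests of the difference of the state's effect between ages, in which each 6-year group is 1 library and the residual degrees of freedom were 1 or 2. From 6 to 22 years, BR effect at 22 minus BR effect at 6 years, edgeR called 122 genes, 34 higher and 88 lower, with 79 in SPD.r, 20 in SSC.u, 15 in Z and 8 in SSC.d. Of 68911 tests 3417 (4.96%) had an unadjusted p under 0.05, no more than the 5% that chance alone gives. This share too pools classes that differed, with Sertoli, which gave no call, above it and SPD.e below it. The genes named by rule were SNRPN (log2 -8.01) and COX3 (4.18) in Z, and FBXW12 (8.46) and PARP15 (3.92) in SPD.r. SNRPN was at 25.6 CPM in 6-year Non-BR and 197 in 6-year BR cells, and at 196 CPM in 22-year Non-BR and 8.06 and 0 in 22-year BR cells. FBXW12 stood out in 22-year BR replicate 1 alone, at 133 CPM. DESeq2 called 27 genes, and the edgeR count was 60 and 64 without 22-year BR replicates 1 and 2. Both 6-year libraries are alone in their group, so these values rest on each of them.

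From 1 to 6 years, BR effect at 6 minus BR effect at 1 year, edgeR called 70 genes, 19 higher and 51 lower, with 54 in SSC.u, 13 in Sertoli and 3 in PMC. Of 21274 tests 1976 (9.29%) had an unadjusted p under 0.05. The genes named by rule were all in SSC.u, UBXN6 (log2 -5.14), TMEM243 (-9.04), PPDPF (-3.51) and PSME3 (-8.50). PPDPF was at 388 CPM in 6-year Non-BR and 30.6 CPM in 6-year BR cells, while TMEM243 and PSME3 had no UMI in 6-year BR cells, so their log2 values are fitted and bound no fold. Without 1-year BR replicate 1 the edgeR adjusted p of all 4 genes was 1.00, and without 1-year BR replicate 2 it was 0.201, 0.171, 0.497 and 0.288 in the order given. DESeq2 called 6 genes. The edgeR count was 4 without either 1-year BR replicate, and 168 and 179 without 22-year BR replicates 1 and 2.

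Shares of spermatid classes moved in opposite directions at 6 and 22 years, and these differences were not tested. SPD.r was lower in the BR than in the Non-BR library at 6 years by 4.17 percentage points (-4.17) and higher in both BR libraries at 22 years, by 5.22 points on average, a difference of 9.39 points. SPD.e was higher at 6 years by 30.7 points and lower in both BR libraries at 22 years (-7.76), a difference of -38.5 points. No group had 4 libraries, so single libraries were not tested as outliers.

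Among the genes lower in adult BR spermatogonia were many of 80 abundant both in spermatids (1000 CPM or more) and in 1-year SSC.u (100 CPM or more), whose median level in SSC.u, relative to 1 year, was 0.792 and 0.831 in the adult Non-BR libraries and 0.306, 0.286 and 0 in 6-year BR replicate 1 and 22-year BR replicates 1 and 2. Their summed level was mostly kept, at 0.903 and 0.956 of 1 year in the Non-BR and 0.855, 0.772 and 0.817 in the BR libraries, so the most abundant of them were less affected. The loss was not confined to spermatogonia or to BR libraries. Genes so defined in somatic classes had medians of 0.498 and 0.647 in Sertoli, 0.723 and 0.501 in Leydig, and 0.615 and 0.471 in PMC of the 6-year and 22-year Non-BR libraries. In the same order of classes the medians were 0.560, 0.548 and 0.428 in 6-year BR replicate 1 and 0.344, 0.286 and 0.273 in 22-year BR replicate 1, lower than in the Non-BR library of the age except for Sertoli at 6 years, and 22-year BR replicate 2 had 0.665 in PMC, higher than Non-BR. Genes under 20 CPM in spermatids were themselves at 0.891 and 0.719 in Sertoli of the 6-year and 22-year Non-BR libraries, so at 22 years the Sertoli value of 0.647 lay little below that of these genes. Age and the loss are therefore mixed in the falls from 1 to 6 years.

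For the loss in spermatogonia the values argued against low depth, since 6-year Non-BR SSC.u thinned to the 32425 UMIs of the shallowest BR library kept a median of 0.764 (0.623 to 0.854 in 100 draws). Spermatid RNA added to Non-BR cells was not decided. Their median stayed under that of 1 year (0.831), but a fall with age could hide an addition. Genes of spermatids alone (1000 CPM or more there, under 5 CPM in 1-year SSC.u) summed to 970 and 2321 CPM in Non-BR SSC.u at 6 and 22 years. In the adult BR libraries they summed to 4102 to 10169 CPM. Some spermatid RNA was therefore present in SSC.u of both states. Removal of free RNA from the counts before deposit may give such gaps, with a highest BR median of 0.306 against 0.966 for genes low in spermatids. Its counterpart at 1 year, where Sertoli RNA would be removed, was absent (27 genes, median 1.08). That value speaks only to a removal applied to every library, and cannot decide on one applied to adult BR libraries alone. For 71 genes of spermatids alone the summed level in SSC.u was taken as a share of that over all cells of the library. In BR libraries this share was 2.39 to 8.65 times the lower Non-BR value, and 0 to 3.76 times without PRM1. PRM1 was higher relative to the other 70 genes in SSC.u than over all cells in each adult library, where over all cells the others came to 0.889 to 1.98 of PRM1. In SSC.u there were 576 UMIs of PRM1 against 19 of the others in 6-year BR replicate 1, and 632 against 109 and 133 against 0 in 22-year BR replicates 1 and 2. In the 6-year and 22-year Non-BR libraries there were 394 against 432 and 503 against 141. This gap was thus present in Non-BR libraries too, but it was larger in each BR library. A response to the BR state stays open, since the median of the 80 genes was lower in each adult BR library than in each Non-BR library, and the concentration of the 22-year falls in genes at 300 CPM or more in spermatids (69.3% of 163 against 9.11% of tested genes, a ratio of 7.61) decides neither way, because with 1 Non-BR library per adult age state and library cannot be told apart.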

How the results depend on the processing

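The use of the planned model of groups with lone libraries was decided after the sample list was seen, the removal of spermatid genes after the data were seen, and the other alternatives were planned. For the values below that moved, the cause was not tested. Groups of age and state had 1 or 2 libraries, and pseudobulks as few as 20 cells, which limits the precision of each contrast.

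BR minus Non-BR over ages gave 16 calls, against 168 with DESeq2, 715 with no count filter, 78 with a 50-cell minimum, 39 without cells under 1000 UMIs and 547 in the model of groups. The replicate block could be fitted only in PMC and SSC.u, where it gave 1 call against 0 in the reported fit. Leaving out 1 library gave 16 to 304, with 275 without 1-year Non-BR replicate 2, 214 and 304 without the 6-year Non-BR and BR libraries, 277 without 22-year Non-BR replicate 2, and 216 and 79 without 22-year BR replicates 1 and 2. 6 minus 1 year gave 2810, against 4350 with no count filter and 1543 to 3318 with 1 library left out (1820 and 1543 without 1-year BR replicates 1 and 2, 1571 without 6-year Non-BR replicate 2). 22 minus 6 years gave 6, against 190 with DESeq2 (124 higher and 66 lower), 474 with no count filter, 37 with a 50-cell minimum, 28 without genes more than 5-fold below another class, 2 without cells under 1000 UMIs, 304 in the model of groups and 30 without spermatid genes, and 5 to 238 with 1 library left out. BR minus Non-BR at 1 year gave 12, against 2 with DESeq2, 465 with no count filter, 40 with a 50-cell minimum, 50 without genes more than 5-fold below another class, 49 without cells under 1000 UMIs and 28 without spermatid genes, and 0 to 47 with 1 library left out (0 and 3 without 1-year BR replicates 1 and 2, 7 without 6-year Non-BR replicate 2, 40 and 47 without 22-year BR replicates 1 and 2). BR minus Non-BR at 22 years gave 303, against 66 with DESeq2, 687 with no count filter, 134 without genes more than 5-fold below another class, 159 without cells under 1000 UMIs and 48 without spermatid genes, and 128 to 375 with 1 library left out (128 and 177 without 1-year BR replicates 1 and 2). BR effect at 22 minus BR effect at 6 years gave 122, against 27 with DESeq2 (13 higher and 14 lower), 430 with no count filter, 79 without genes more than 5-fold below another class and 49 without cells under 1000 UMIs, and 60 to 122 with 1 library left out. BR effect at 6 minus BR effect at 1 year gave 70, against 6 with DESeq2, 440 with no count filter, 150 with a 50-cell minimum and 108 without genes more than 5-fold below another class, and 4 to 179 with 1 library left out. RLE factors kept every one of these counts within 1.5 times, with 39 higher and 54 lower in the last contrast in place of 19 and 51.

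Gene list tests, BR minus Non-BR over ages, gave 26 calls and 19 to 34 with 1 library left out. In PMC and SSC.u alone, where the replicate block could be fitted, they gave 4 calls, and 1 with the block. Gene list tests, 6 minus 1 year, gave 30 and 24 to 32, and gene list tests, 22 minus 6 years, 28 and 17 to 32 (17 without 6-year Non-BR replicate 2). All 3 gave 0 with an estimated correlation, a setting that also failed the free spermatid RNA probe and so cannot decide against a list. The reported setting called 15 to 34 lists between states in the other splits within age. Its 26 calls over ages, however small their p, therefore do not set the real states apart. Germ cell share of cells, BR minus Non-BR, kept its direction, with a logit of 0.818, 1.13 among cells with at least 1000 UMIs, 0.633 in the paired comparison by replicate block, 0.513 to 1.05 with 1 library left out, and 5.62 in percentage points. No share could pass in any of these settings, so they say nothing about its stability past a threshold. Of 419 named gene results 142 were calls, and none of these calls reversed direction in any alternative. Changes of direction were not counted for results that were not calls. Over all named results and alternatives, 5027 values kept their side of the threshold, 301 fell short of it and 245 newly passed it. Of 142 named calls, 84 ended under at least 1 alternative and 71 when 1 library was left out. Scaling moved the median of all genes by over 0.1 on the log2 scale in Sertoli cells (-0.11 at 6 minus 1 year and 0.21 at 22 minus 6 years, with RLE or DESeq2, and 0.11 with either at BR effect at 6 minus BR effect at 1 year) and in PMC (0.12 with RLE and 0.13 with DESeq2 at BR effect at 22 minus BR effect at 6 years).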

Other observations

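Of the tests below, the other splits of the libraries were planned, and the tests of free spermatid RNA in Sertoli cells and of pericytes in PMC were chosen after the result was seen.

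Spermatid RNA was found in somatic cells of adult libraries, so the 1062 rises of Sertoli cells from 1 to 6 years were weighed against it. Over 50% of the rises would lie more than 5-fold below a germ cell class if such RNA were their main source, and 18.8% did, 200 of 1062, against 49.4% of falls and 25.2% of tested genes. Free RNA may so account for part of the rises, such as PRM1, but the value argues against it as the main source. Age and maturation of the cells stay open as an untested biological explanation.

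Smooth muscle genes were higher in PMC of both 1-year BR libraries than in the 1 Non-BR library, and more pericytes or vascular smooth muscle cells within PMC could give this. The median log2 difference of pericyte markers was 3.13, with 3 of 5 markers higher. Peritubular myoid markers were higher in 8 of 9, with a median of 1.34, while stromal markers had a median of 0.164 and endothelial markers 0.181. With 5 pericyte markers and 1 Non-BR library, a change in the mix of cells and a change within myoid cells cannot be told apart, and immediate-early genes, higher in 16 of 17 members in the same PMC, leave a difference in dissociation open as well.

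The 8 libraries allow 18 splits within age, too few for a share under 0.05. The real split gave 16 gene calls between states over ages. All 16 lay in L and Z, whose fits hold adult libraries only, so relabelling 1-year libraries could not change them. The 3 splits at or above the real count, the real one among them and the highest at 22, all kept the real adult labels. Splits with other adult labels gave at most 12. Only 6 arrangements of the adult libraries exist, too few for a share under 0.05, so chance is not excluded. For gene lists the real split gave 26 calls and the others 15 to 34, with 9 splits at or above the real count, so list calls did not set the real split apart.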
